A study of Mus musculus with 6 samples.

How the data were processed

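Whole ovaries of 8-month-old mice, 3 WT and 3 FORKO samples with both ovaries pooled, were profiled on Affymetrix Mouse Genome 430 2.0 arrays. The deposited values are MAS5 signals, an array intensity on a linear scale with 1 value per probe set, per the submitters' processing notes; the scaling target, masking and detection calls are not given in the sources used here. The deposited intensities ran from 0 to 9781, 6.66% of them were under 1, and 10 were 0. The arrays did not share 1 trimmed mean. Groups and replicate numbers were taken from the sample titles, which match the genotype field; the free-text description and treatment fields of the FORKO samples instead speak of wild-type mice, a conflict the labels do not resolve. The labels call the samples biological replicates but do not say how many mice each RNA sample came from, so p-values measure the spread between these samples. No 2 arrays of a group held identical values (0 of 6 pairs). The Pearson correlation of log2 signals across probe sets was 0.966 to 0.969 within WT, 0.934 to 0.936 between FORKO replicate 1 and the other FORKO arrays, and 0.976 between FORKO replicates 2 and 3.

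Each array was scaled to the same mean after trimming 2% at each end (factors 0.895 to 1.09), and log2(signal + pseudocount) was taken with the pooled 25th percentile, 5.73, as pseudocount. The 64 control probe sets were left out, and probe sets were kept where the mean scaled signal reached the median of all means, 20.4. This left 22506 probe sets, which were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend, two-sided) and Benjamini-Hochberg adjustment at 0.05. No replicate block was in the main design. Figures were drawn with matplotlib 3.10.9. On simulated data with 200 changed probe sets among 22506 in each of 10 runs, 50.4% of changes of 1 and 98.0% of changes of 2 on the log2 scale were recovered, and 7.77% of calls were false. For lists of 20 independent simulated genes, camera called 10 of 10 lists shifted by 0.7 and 1 of 100 unshifted lists. In the real lists the estimated correlation between genes reached 0.599 for cell division and 0.799 for lymphocyte genes. The simulated rates therefore do not apply to camera's p values for such lists.

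The platform annotation gave 1 gene symbol for 34958 probe sets, several for 932 and listed none for 9211. Of the first, 34754 matched the GRCm38.p6 gene table by Entrez identifier, and no symbol changed; that table was used only for names and for which genes neighbour each other. Genes were not named from probe sets with several symbols. Of the 372 probe sets that passed, 317 had 1 symbol, 18 several and 37 none listed. The probe set with the highest mean signal stood for a gene. The 26 gene lists, the main design and the rule for named genes were fixed before the data were examined. That rule took Fshr, the 15 largest rises and 15 largest falls among named genes that passed with groups that did not overlap, leaving out clone and predicted gene names, and in each list up to 4 members that passed with the largest change, or the 2 largest changes where none passed. Of the 73 genes named so, 25 had other probe sets past the filter (36 in all), and 0 of these changed in the opposite direction. Not all of these probe sets passed. For some genes that passed no other probe set did: Adcyap1 (limma adjusted p = 0.0751), Btg2 (0.0502), Ccn1 (0.150) and Cdkn1b (0.179). The same held for Gpm6a (limma adjusted p = 0.231), Klf4 (0.281), Scd1 (0.860) and Timp2 (0.0789 to 0.333). A few further genes, such as Inhba, Fst, Sfrp4, Foxl2 and Amhr2, are given per array and were chosen after their values were seen.

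Lists were tested with camera (preset correlation 0.01, and estimated per list), fry, and per-gene counts adjusted over all genes tested and over the list alone. Some lists share genes, and the ovary itself expresses many members of the lists for other tissues, so a list names a known site of expression and not a cell present in these samples. Both groups carry replicate numbers 1 to 3, which the labels do not tie to a litter or day. The deviations of same-numbered arrays from their group means correlated at 0.195, 0.134 and 0.358 for numbers 1, 2 and 3, all above 0.1, and 6 of 6 arrays correlated best with their own number. By the rule that every pair must exceed 0.1, the numbers were taken to pair the samples, from the data and not from the labels. Of the 6 possible matchings only 1 met this rule, and so few matchings cannot exclude chance. Results with the block therefore rest on a pairing chosen from these same data. With the block, 691 probe sets passed, against 372 without it, and 363 were shared.

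Alternatives covered the normalization (quantile, as deposited, same median), the pseudocount, the dim filter, the variance model, the kinds of probe sets, the block, each array left out in turn, the correlation within a list and the probe set standing for a gene. Scaling to the bacterial hybridisation spikes was added after seeing the data. The spikes read 717 ± 48.6 in WT and 635 ± 36.7 in FORKO arrays (SD, n = 3) after the main scaling.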

Results

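Gene expression was measured in whole ovaries of 8-month-old female mice that lacked the receptor for follicle-stimulating hormone (FORKO) and of wild-type (WT) mice from the same breeding of heterozygotes on the 129T2/SvEmsJ background. Both ovaries were pooled for each RNA sample. Each of the 3 WT and 3 FORKO samples, given as biological replicates in the labels, was hybridised to its own Affymetrix Mouse Genome 430 2.0 array. The deposited signals had a trimmed mean of 80.6 to 98.4 and a median of 17.7 to 23.5 per array. After scaling to 1 trimmed mean, 22506 probe sets passed the filter on dim signals and were tested. Arrays give no counts, and the number of arrays limits the precision. Signals below are scaled signals, given as mean ± SD (n = 3), and each log2 change is FORKO minus WT on the scale log2(signal + 5.73), which understates the change of dim probe sets.

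The first comparison checked the deleted gene. Fshr, the receptor for follicle-stimulating hormone on granulosa cells, has 1 probe set, and its signal was 92.6 ± 30.3 (n = 3) in WT and 8.05 ± 5.93 (n = 3) in FORKO ovaries. The WT arrays read 99.6, 59.4 and 118.8, and the FORKO arrays read 1.2, 11.2 and 11.7, so that all FORKO arrays lay below all WT arrays. The log2 change was -2.90 ± 0.39 (SE; limma adjusted p = 0.0102), and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 arrays can give. The adjusted p was 0.0526 without WT replicate 1 and 0.0598 without WT replicate 3. Where the probe set lies relative to the deleted part of the gene is not known here, so its signal checks the labels only as far as the deletion covers it.

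The main question was which genes differ between ovaries with and without the receptor. The largest rise was that of Lcn2, the iron-siderophore carrier lipocalin 2, from 9.74 ± 6.68 to 897 ± 740 (n = 3 in each group; log2 change 5.58 ± 0.57, SE; limma adjusted p = 0.00296). Ptgds, the lipocalin-type prostaglandin D synthase, rose from 24.6 ± 6.68 to 1297 ± 1091 (log2 change 5.00, limma adjusted p = 0.00623). The kallikrein genes Klk1b27, Klk1b21 and Klk1b24 rose by 4.52, 3.85 and 2.90 on the log2 scale, and Sult1e1, the oestrogen sulfotransferase, rose by 4.24. Penk, which encodes the opioid precursor proenkephalin, rose from 162 ± 8.61 to 1324 ± 773, and Aldh1a7, an aldehyde dehydrogenase, from 156 ± 5.08 to 1520 ± 615. The other 7 of the 15 largest rises were those of Ces1d, a carboxylesterase (3.99), Nxf3 (3.81), Svs5, a seminal vesicle secretory protein (3.28), Mia (3.07), Sphkap (2.98), Wfdc18 (2.95) and the desmosomal cadherin Dsc3 (2.80).

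The largest fall was that of Adcyap1, which encodes the neuropeptide PACAP, from 328 ± 187 (n = 3) to 0.3, 26.3 and 18.4 on the 3 FORKO arrays ( log2 change -4.16 ± 0.60, SE; limma adjusted p = 0.0129). Car3, carbonic anhydrase 3, fell from 1049 ± 109 to 56.4 ± 19.2 and had the lowest adjusted p among the named genes (log2 change -4.12, limma adjusted p = 1.62e-04). Tmem178 fell from 2036 ± 213 to 176 ± 73.9 (log2 change -3.57, limma adjusted p = 0.00104). Cemip, which acts in hyaluronan breakdown, changed by -3.61, the cartilage oligomeric matrix protein Comp by -3.04, and the thrombospondin Thbs4 by -2.68. The 15 largest falls also held Fshr, Cpxm2 (-2.85), the apolipoprotein Apoa4 (-2.37), Insyn2b (-2.27), Ankrd63 (-2.17), the postsynaptic scaffold Homer2 (-2.15), the proton pump Atp12a (-2.08), Gsg1l (-1.93) and the ephrin receptor Epha3 (-1.92).

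In all, 372 probe sets passed limma's test at an adjusted p of 0.05, of which 238 were higher and 134 lower in FORKO ovaries. A change of at least 2-fold was seen for 331 of these, 212 of them higher and 119 lower. With 1 probe set standing for each gene, 146 genes rose and 94 fell among the 11199 tested. The groups did not overlap for any of the 372 probe sets, and 20.4% of all tested probe sets had no overlap, where chance gives 10%. The replicate numbers paired the samples by the rule on their deviations, which does not exclude chance, and with the number as a block the count was 691. The share of higher calls was 64.0%, against 50.6% when arrays were scaled to the same median and 84.0% when they were scaled to the bacterial spikes, a setting chosen after seeing the data that moved the median of all genes by 0.16 on the log2 scale. The count was 112, 62 and 83 without WT replicates 1, 2 and 3, and 864, 316 and 143 without FORKO replicates 1, 2 and 3. Each of the 372 kept its sign in all 6 of these fits, which was fixed beforehand because the groups did not overlap. Of the 15 largest rises, 12 passed in all 6 fits, the others being Sult1e1, Svs5 and Dsc3; of the 15 largest falls, the 5 that passed in all 6 were Car3, Tmem178, Cpxm2, Thbs4 and Homer2. Of the 27 genes below that passed only as members of a gene list, 6, 3 and 5 passed without WT replicates 1, 2 and 3, and 27, 17 and 9 without FORKO replicates 1, 2 and 3; only Serpina3n, Oosp1 and Rfpl4 passed in all 6.

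**Figure D1:**
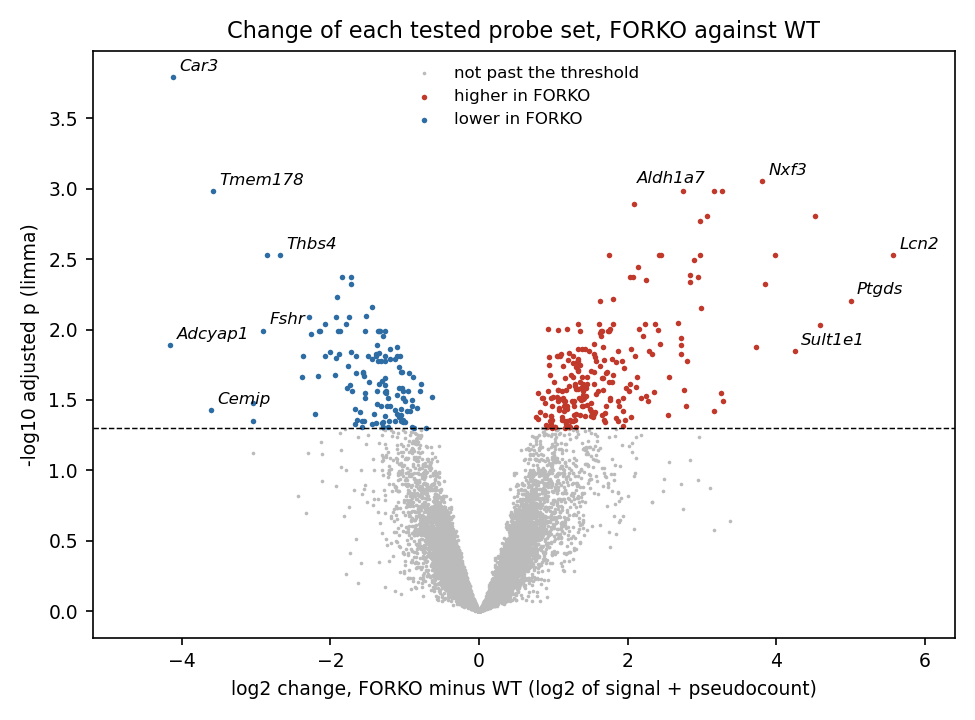
Each point is 1 of the 22506 tested probe sets, with its log2 change (FORKO minus WT) on the horizontal axis and -log10 of limma's adjusted p on the vertical axis; the dashed line is an adjusted p of 0.05. Above the line lie 238 probe sets higher in FORKO (red) and 134 lower (blue), with Lcn2 farthest right at 5.58 and Adcyap1 farthest left at -4.16.

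**Figure D2:**
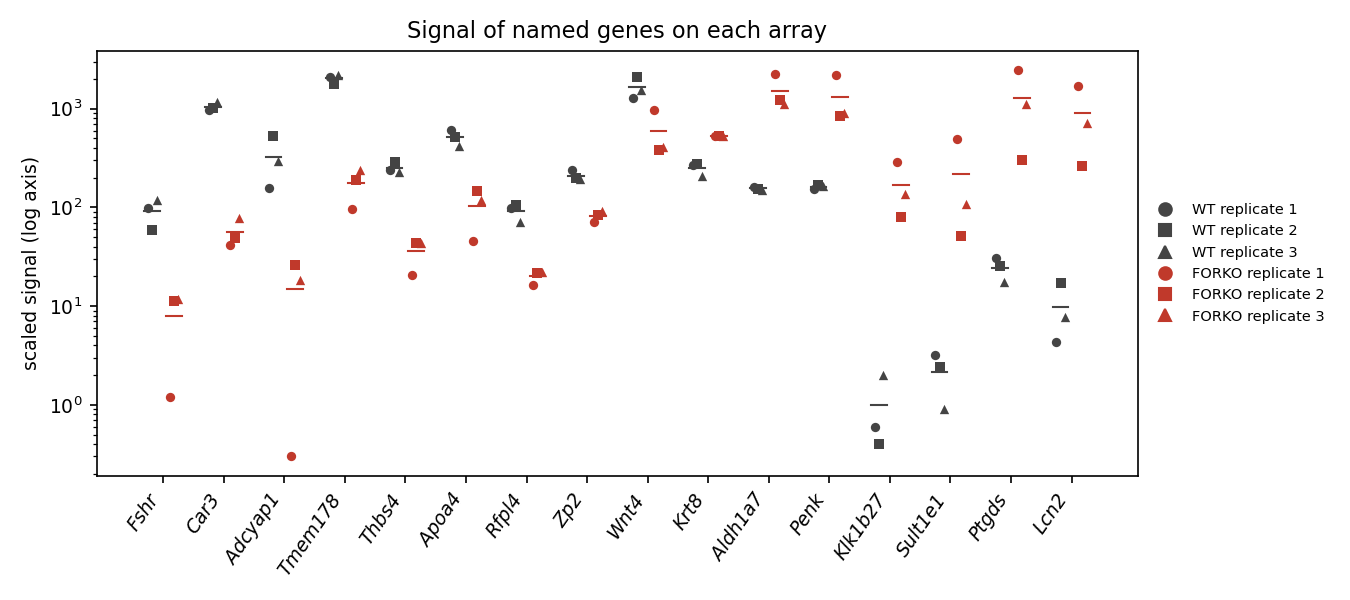
Scaled signal (log axis) of 16 named genes on each of the 3 WT (grey) and 3 FORKO (red) arrays, with 1 symbol per replicate number and a bar at each group's mean. Fshr lies at 59.4 to 118.8 in WT and at 1.2 to 11.7 in FORKO, and the rises of Lcn2, Ptgds, Sult1e1 and Klk1b27 are highest in FORKO replicate 1.

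Genes made by oocytes had negative changes in FORKO ovaries. Of 14 measured members of the oocyte list, 5 fell and 9 did not pass, and all 14 had a negative change with a median of -0.77 on the log2 scale. Rfpl4 fell from 92.1 ± 18.6 to 20.1 ± 3.20 (n = 3 in each group; log2 change -1.91), Oosp1 by 1.52, the zona pellucida gene Zp2 by 1.29 and the maternal-effect gene Zar1 by 1.05 on the log2 scale. Adjusted over the list alone, 10 members passed. The list shifted down in limma's camera test (adjusted p = 1.01e-10), which was lost with an estimated correlation (adjusted p = 0.237 with an estimated correlation). None of 29 measured cell division genes passed the limma test, but all 29 had a negative change, with a median of -0.57. Ccne2, cyclin E2, read 121 ± 33.1 in WT and 46.3 ± 18.2 in FORKO, and the mitotic checkpoint kinase Bub1 read 94.9 ± 32.6 and 39.8 ± 23.4 (n = 3 in each). With the replicate block both passed, at adjusted p values of 0.0182 and 0.0400. Adjusted over the list alone, 9 passed, and camera's adjusted p was 5.05e-09, against an adjusted p of 0.311 with an estimated correlation. FORKO replicate 1 had the lowest medians of both lists (-1.20 and -1.24), against -0.67 and -0.71 for oocyte genes and -0.26 and -0.34 for cell division genes in replicates 2 and 3, and without it the median of cell division genes was -0.28.

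Transcripts of some granulosa and luteal genes differed between FORKO arrays. Of 22 measured granulosa and growing follicle genes, Fshr fell and 21 did not pass (5 passed when adjusted over the list alone); the median change was -0.39 (camera adjusted p = 0.359). The list's median against WT was -1.33 in FORKO replicate 1 but 0.36 and 0.28 in replicates 2 and 3. Without FORKO replicate 1 the list's median was 0.33 (camera adjusted p = 0.316), Esr2 rose, and Fshr, Nr5a2 and Nppc fell. With the replicate block 4 members passed limma's test: Fshr and Nr5a2 (adjusted p = 0.0133 and 0.0421) were lower, and Kitl and Amhr2 (0.0423 and 0.0346) higher. Inhba, the activin and inhibin subunit βA, read 54.2 in FORKO replicate 1, against 3867 and 3756 in replicates 2 and 3 and 3103 ± 1153 (n = 3) in WT. Fst, which encodes the activin-binding protein follistatin, read 42.0, 1832 and 1766 in FORKO replicates 1, 2 and 3. Foxl2, a transcription factor of granulosa cells, read 849, 872 and 819 there, and Amhr2, the receptor for anti-Müllerian hormone, 2840, 2128 and 2941. Of 13 luteal genes, Fdx1, the electron donor of steroid hydroxylases, fell from 4640 ± 158 to 2993 ± 249 and the cell cycle inhibitor Cdkn1b from 158 ± 27.6 to 83.2 ± 3.47 (n = 3 in each; limma adjusted p = 0.0299 and 0.0498). The other 11 luteal genes did not pass, 3 members passed when adjusted over the list alone, and the list shifted down (median -0.51, camera adjusted p = 0.0201; adjusted p = 0.311 with an estimated correlation). Without FORKO replicate 1 the luteal list did not pass (adjusted p = 0.147), although its median was -0.45; without WT replicate 2 it passed with a median of -0.24.

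No member passed among 11 theca and interstitial genes of steroid synthesis (1 when adjusted over the list alone; median -0.29, camera adjusted p = 0.0598). Star, the cholesterol carrier of steroidogenic mitochondria, read 1328 ± 620 in WT and 676 ± 131 in FORKO (n = 3 in each) and passed with the replicate block (adjusted p = 0.0418), while Ephx2 read 1139 ± 378 and 945 ± 655. The list's camera test passed without WT replicate 2 (adjusted p = 0.0281), without FORKO replicate 2 (0.0483) and without FORKO replicate 3 (0.0237). None of 9 ovulation and cumulus expansion genes passed (5 when adjusted over the list alone; median -0.01, positive with spike scaling; camera adjusted p = 0.433). Pgr, the progesterone receptor, read 50.2 ± 20.5 in WT and 18.6 ± 7.75 in FORKO, and Cebpb, a transcription factor of ovulating follicles, read 350 ± 147 and 159 ± 10.4; Cebpb passed with the block (adjusted p = 0.0385). Of 23 hormone receptors and ligands, Fshr fell and 22 did not pass (4 when adjusted over the list alone; median -0.02, positive with spike scaling; camera adjusted p = 0.911).

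**Figure D3:**
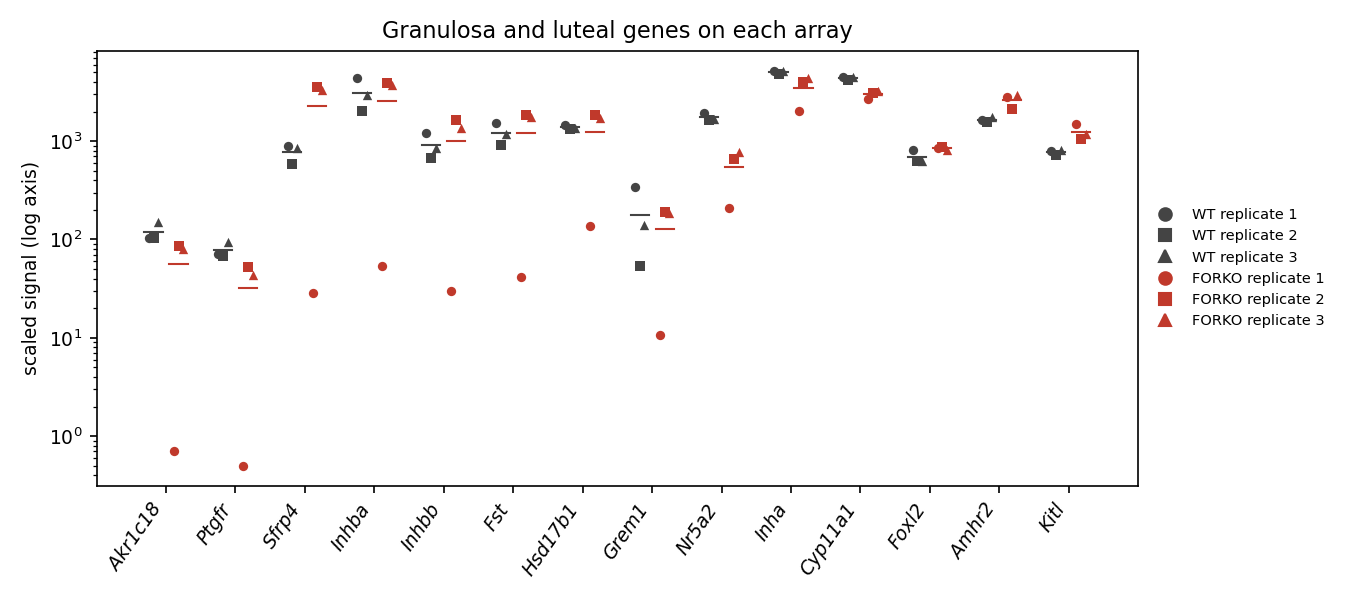
Scaled signal (log axis) of 14 granulosa and luteal genes on each of the 3 WT (grey) and 3 FORKO (red) arrays, with a bar at each group's mean. FORKO replicate 1 lies far below the other arrays for Inhba (54.2), Fst (42.0) and Sfrp4 (28.9), and near them for Foxl2 (849) and Amhr2 (2840).

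Lists of epithelial genes had positive medians in FORKO ovaries, but few of their members passed. Of 17 surface epithelium genes, 3 rose and 14 did not pass (9 when adjusted over the list alone). The keratins Krt8 and Krt18 rose from 252 ± 36.0 to 530 ± 6.12 and from 130 ± 23.1 to 298 ± 72.9 (n = 3 in each), and the membrane glycoprotein gene Gpm6a rose by 1.22 on the log2 scale (limma adjusted p = 0.0155, 0.0321 and 0.0496). The list's median was 0.86 (camera adjusted p = 7.06e-08; adjusted p = 0.276 with an estimated correlation), and it was 1.53 in FORKO replicate 1 against 0.32 and 0.64 in replicates 2 and 3 (0.53 in the fit without replicate 1). Tight junction genes shifted up (16 measured, median 0.44, camera adjusted p = 0.00337; adjusted p = 0.311 with an estimated correlation), but the member that passed, the claudin gene Cldn1, fell by 1.48 on the log2 scale, and 15 did not pass (5 when adjusted over the list alone). Without FORKO replicate 1 the tight junction list did not pass (camera adjusted p = 0.0571, median 0.24); that array's own median was 0.85, against 0.24 and 0.22 in replicates 2 and 3. limma's fry did not call the surface epithelium or tight junction list (adjusted p = 0.105 and 0.143). None of 5 oviduct and ciliated epithelium genes passed (4 when adjusted over the list alone), all 5 had a positive change, and their median was 1.34 (camera adjusted p = 5.36e-04; adjusted p = 0.153 with an estimated correlation). Ovgp1, the oviductal glycoprotein, read 26.6 ± 12.1 in WT and 27.2, 247 and 184 in FORKO replicates 1, 2 and 3, and Wfdc2 read 9.25 ± 6.69 and 44.0 ± 9.21 (n = 3 in each). Of 12 genes known from Sertoli and Leydig cells of the testis, Ptgds and the β-defensin gene Defb19 rose, the latter from 228 ± 54.7 to 752 ± 284, and 10 did not pass (6 when adjusted over the list alone). The list's median was 0.67 (camera adjusted p = 6.19e-04; adjusted p = 0.273 with an estimated correlation), with 1.52 in FORKO replicate 1 and 0.21 and 0.66 in replicates 2 and 3; it was 0.36 without replicate 1 and 1.04 without replicate 2.

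Complement and acute phase genes had positive changes in FORKO ovaries. The medians of complement, antigen presentation, macrophage and lymphocyte genes were all highest in FORKO replicate 1. All 11 measured complement and acute phase genes had a positive change (median 1.21), of which Lcn2, Serpina3n and Cfi rose and 8 did not pass (9 when adjusted over the list alone). Serpina3n, a serine protease inhibitor, rose from 41.5 ± 5.25 to 194 ± 7.08, and complement factor I, Cfi, from 31.1 ± 6.24 to 90.9 ± 26.9 (n = 3 in each; limma adjusted p = 0.00128 and 0.0260). Camera's adjusted p was 5.05e-09 (adjusted p = 0.209 with an estimated correlation). Of 24 MHC and interferon response genes, the class I gene H2-D1 rose from 963 ± 69.5 to 2320 ± 789 and 23 did not pass (6 when adjusted over the list alone; median 0.79, camera adjusted p = 2.21e-07, adjusted p = 0.376 with an estimated correlation). None of 21 macrophage genes passed (0 when adjusted over the list alone), and all 21 had a positive change (median 0.38, camera adjusted p = 7.21e-04; adjusted p = 0.399 with an estimated correlation). Gpnmb read 74.5 ± 10.8 in WT and 556.6, 96.0 and 158.8 in FORKO replicates 1, 2 and 3, and the integrin gene Itgb2 read 97.4 ± 22.4 in WT and 257 ± 199 in FORKO. None of 9 lymphocyte genes passed (4 when adjusted over the list alone; median 0.85, camera adjusted p = 0.00282, adjusted p = 0.396 with an estimated correlation). The chemokine gene Ccl5 read 15.5 ± 7.28 in WT and 98.7 ± 99.6 in FORKO and passed with the block (adjusted p = 0.0421), and the interleukin receptor gene Il7r read 35.8 ± 4.11 and 161 ± 132. The medians of FORKO replicates 1, 2 and 3 were 1.69, 0.84 and 0.93 for complement, 1.65, 0.15 and 0.60 for MHC, 1.17, -0.05 and 0.18 for macrophage, and 1.67, 0.30 and 0.57 for lymphocyte genes. Without FORKO replicate 1 the complement list passed with a median of 0.88. The MHC list also passed then, with a median of 0.42 and 4 members that rose (H2-K1, H2-D1, B2m and Cxcl9). In that fit the macrophage (0.04, camera adjusted p = 0.300) and lymphocyte lists (0.43, camera adjusted p = 0.126) did not pass. The macrophage median was 0.64 without FORKO replicate 2. Of 4 mast cell genes, too few for the list test, Hdc, which makes histamine, rose from 187 ± 36.6 to 351 ± 24.5 (limma adjusted p = 0.0476) and 3 did not pass (1 when adjusted over the list alone). No gene of the erythroid list was measured above the dim filter.

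**Figure D4:**
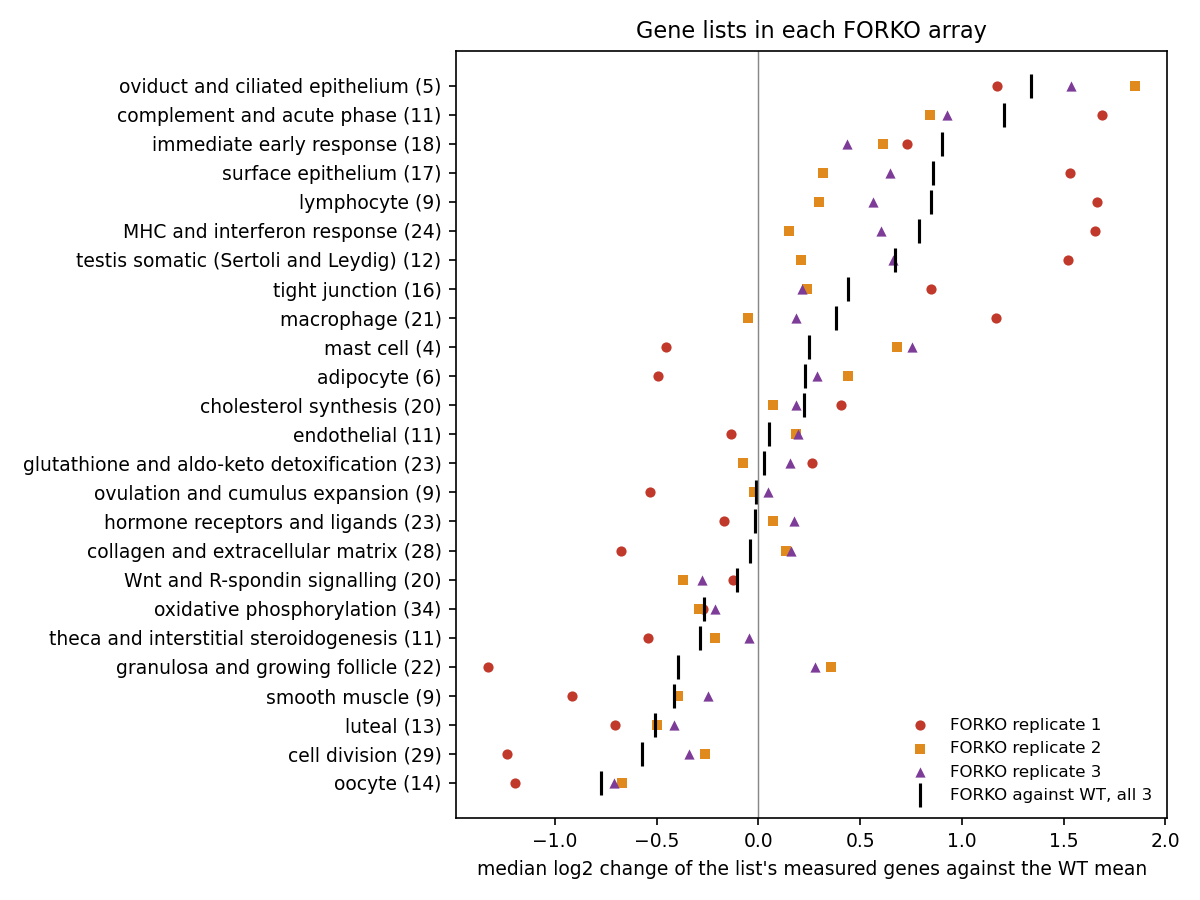
Median log2 change of the measured members of 25 gene lists (number of members in brackets), for each FORKO array against the WT mean (coloured symbols) and for the fit over all arrays (black bar, the median of the members' fitted changes, which need not lie between the arrays' medians). FORKO replicate 1 lies lowest for granulosa (-1.33), cell division (-1.24) and oocyte genes (-1.20), and highest for complement (1.69), lymphocyte (1.67) and MHC genes (1.65).

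Genes of Wnt signalling and contractile cells included falls. Of 20 Wnt and R-spondin genes, Wnt4, a signal needed for ovarian development, fell from 1651 ± 424 to 589 ± 330 and Rspo2, which enhances Wnt signals, from 125 ± 6.05 to 40.2 ± 9.71 (n = 3 in each; limma adjusted p = 0.0492 and 0.0102), and 18 did not pass (5 when adjusted over the list alone). Wnt4 did not pass with the replicate block (adjusted p = 0.0559). The list did not pass camera's test (median -0.11, positive with spike scaling; adjusted p = 0.0598), but limma's fry called it (adjusted p = 0.016). Of 9 smooth muscle genes, the actin gene Actg2 fell from 76.8 ± 10.2 to 35.0 ± 6.67 and 8 did not pass (3 when adjusted over the list alone). The list shifted down (median -0.41, camera adjusted p = 0.0314; adjusted p = 0.276 with an estimated correlation), but not without WT replicate 3 (0.0721) or FORKO replicate 1 (0.147), which had the lowest median (-0.91, against -0.39 and -0.25 in replicates 2 and 3); the list's median was -0.25 without that array and -0.24 with spike scaling. Of 28 collagen and matrix genes, Col18a1, which encodes a basement membrane collagen, and the metalloproteinase inhibitor Timp2 rose by 1.55 and 1.24 on the log2 scale, and 26 did not pass (3 when adjusted over the list alone; median -0.04, positive with spike scaling). No other probe set of Timp2 passed (limma adjusted p = 0.0789 to 0.333). Camera's adjusted p for the collagen and matrix list was 0.845, with a direction up against its negative median. Without FORKO replicate 1 it was 0.0115, with a positive median of 0.14, 5 members that rose (Col4a1, Col4a2, Col18a1, Fn1, Timp2) and 1 that fell (Postn). None of 11 endothelial genes passed (0 when adjusted over the list alone; median 0.05, negative with median scaling; camera adjusted p = 0.299). The von Willebrand factor gene Vwf read 111 ± 22.4 in WT and 252 ± 117 in FORKO and passed with the block (adjusted p = 0.0317), and Esam read 164 ± 9.87 and 216 ± 49.5. Of 6 adipocyte genes, Scd1, stearoyl-CoA desaturase, rose from 389 ± 115 to 873 ± 139, Car3 fell, and 4 did not pass (2 when adjusted over the list alone; median 0.23, mean -0.46, camera direction down with an adjusted p of 0.836). The other probe set of Scd1 did not show this rise (log2 change 0.14, limma adjusted p = 0.860).

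Immediate early genes had a positive median and genes of oxidative phosphorylation a negative one, with few or no members that passed. Of 18 immediate early genes, 4 rose and 14 did not pass (9 when adjusted over the list alone): the transcription factor genes Klf4 and Fos by 1.84 and 1.75 on the log2 scale, and Ccn1 and Btg2 by 1.33 and 1.30. The list's median was 0.90 (camera adjusted p = 1.54e-06; adjusted p = 0.153 with an estimated correlation); it was 0.58 without FORKO replicate 1, and 0.73, 0.61 and 0.44 on FORKO arrays 1, 2 and 3. None of 34 oxidative phosphorylation genes passed (0 when adjusted over the list alone), and 32 had a negative change (median -0.27, camera adjusted p = 1.71e-06; adjusted p = 0.239 with an estimated correlation). With spike scaling this median was -0.10. The complex I subunit gene Ndufb3 read 1196 ± 390 in WT and 753 ± 75.4 in FORKO, and the complex III subunit gene Uqcrfs1 read 750 ± 130 and 529 ± 128 (n = 3 in each). Of 20 cholesterol synthesis genes, Tm7sf2, a sterol reductase, rose from 109 ± 3.69 to 228 ± 34.7 and 19 did not pass (1 when adjusted over the list alone), while 17 had a positive change (median 0.22, camera adjusted p = 0.00109; adjusted p = 0.153 with an estimated correlation). The cholesterol median was 0.14 without FORKO replicate 1 and 0.39 with spike scaling. Of 23 glutathione and aldo-keto detoxification genes, the glutathione transferase gene Gsta3 rose from 43.3 ± 10.1 to 195 ± 132 and 22 did not pass (5 when adjusted over the list alone). That list's median was 0.03, negative for signals as deposited and with median scaling, and its camera adjusted p was 0.153, or 0.0340 without FORKO replicate 2.

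Of 24 lists with at least 5 measured members, 15 passed camera's test with the preset correlation of 0.01, 10 of them higher and 5 lower in FORKO ovaries. With the correlation estimated per list, 0 passed, the lowest adjusted p was 0.153, and 5 lists had an unadjusted p under 0.05. The oviduct and cholesterol synthesis lists lost their call although their estimated correlations were -0.15 and -0.04, below the preset 0.01. Correlation between genes does not account for these losses, and their cause was not tested. A list that did not pass in this way is therefore not shown to be unshifted. limma's fry, which tests whether a list's genes move one way on balance, called 7 lists, and its test for change in either direction called 16. The 7 were the oocyte, cholesterol synthesis, oviduct, immediate early, oxidative phosphorylation, complement and Wnt lists. Among lists that passed camera, fry did not call cell division (adjusted p = 0.143), MHC (0.221), macrophage (0.31), lymphocyte (0.271) or luteal genes (0.129). Nor did it call smooth muscle (0.0647), testis somatic (0.0623), surface epithelium or tight junction genes.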

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

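Spike scaling and the count of probe sets over splits were chosen after seeing the data, and all else here before. The 372 probe sets kept their sign in each of the 19 other settings in which they were tested. Since the groups did not overlap, only the changes of scaling could have turned a sign. The count of 372 stayed within 1.5 times except with no filter on dim probe sets (221, and 205 of at least 2-fold change), the brightest 25% of probe sets (191 and 161; fewer probe sets, with Fshr left out), array weights (712), the replicate block (691) and spike scaling (589); apart from the smaller set the cause was not tested. With 1 array left out the count ran from 62 to 864, that of at least 2-fold change from 62 to 607, the lists that passed from 11 to 17, and the Fshr change from -3.17 to -2.47. Fshr changed by -2.83 without WT replicate 1 and -2.71 without WT replicate 3, where it did not pass. Of 15 lists, 0 passed with an estimated correlation. Ephx2, which did not pass, turned from -0.61 to 0.26 without FORKO replicate 1 and was -1.13 without FORKO replicate 2; the cause was not tested. With the block 15 lists passed. Among the 73 genes named by the rule, Wnt4 was lost and Bub1, Ccl5, Ccne2, Cebpb, Star and Vwf gained, and no other call changed. With array weights camera did not pass for luteal (adjusted p = 0.0541), lymphocyte (0.0510), macrophage (0.0541) and smooth muscle genes (0.0653). Luteal and smooth muscle genes did not pass in the brightest 25% (0.105 and 0.279), nor luteal genes with all probe sets of a gene averaged (0.0833). Wnt genes passed with no filter (0.0294), in the brightest 25% (0.00332) and with spike scaling (0.00983), and theca genes with no filter (0.0492). Medians of lists that passed moved by more than 1.5 times with no filter (lymphocyte 0.42, oviduct 0.47, smooth muscle -0.25, testis somatic 0.39), a larger pseudocount (oviduct 0.89), the brightest 25% (testis somatic 1.56, luteal -0.15), array weights (cholesterol 0.15, macrophage 0.10, testis somatic 0.42) and all probe sets averaged (luteal -0.16). Signals near the pseudocount of 5.73 limit the change that dim genes can show. Of the 10 splits of the 6 arrays into 3 and 3, only 1 gave 372 or more probe sets, the real one, and the highest other gave 0 (215 to 2202 at an unadjusted p under 0.05, against 3284). For lists 1 split reached 15, the real one, with 2 to 13 in the others. The 3 other splits that also part all pairs gave 0 probe sets and up to 13 lists. With 10 splits the share cannot fall below 0.05.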

Other observations

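The tests of FORKO replicate 1, of oviduct and of the count of probe sets over splits were chosen after the result was seen; those of kallikrein probe sets, Y-linked genes, Fshr's neighbours and lists over splits were chosen before. Further genes named in the next paragraph, and its test of families, were chosen after their values were seen.

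Genes outside the fixed lists passed as well, picked from the called genes and not tested as groups. Of the genes that fell, 11 more are known from oocytes, among them the homeobox genes Obox2 (107 ± 2.38 in WT, 40.0 ± 17.1 in FORKO; n = 3 in each) and Obox5 (56.1 ± 8.86 and 20.6 ± 5.45), the secreted protein genes Oosp2 and Oosp3, Nlrp4b, Bcl2l10 and Sall4. Their log2 changes lay between -1.53 and -1.22, with limma adjusted p values of 0.0147 to 0.0472, and 0 of the 11 passed in all 6 fits that left out 1 array. Angpt2, which loosens vessel walls, rose from 110 ± 25.7 to 469 ± 107, and the adhesion molecule Vcam1 rose from 288 ± 92.5 to 1252 ± 96.6 (limma adjusted p = 0.00426 and 0.00358), both past the threshold in all 6 such fits. Angpt4 and Ramp1 also rose but passed in 3 of those 6 fits, Icam1 in 2, and Cd34, Procr and Calcrl in 1 (log2 changes 0.93 to 2.55). The fixed endothelial list did not shift (0 of 11 passed, median 0.05, camera adjusted p = 0.299), so these genes show no change of vessels as a group. Col4a4, Col4a6 and Lama2, of basement membranes, rose by 1.30, 1.44 and 1.09 and passed in 3, 1 and 3 of the 6 fits, and the cell cycle inhibitor Cdkn1a rose by 1.68 and passed in 1. Of 343 families of genes with the same symbol stem and at least 5 measured members, 0 held more calls than the other genes after adjustment (one-sided Fisher's exact test); the keratins had the lowest p (5.03e-04, adjusted 0.172), with Krt8, Krt18 and Krt79 of 8 measured genes higher.

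FORKO replicate 1 stood apart in follicle genes: 12 of 35 granulosa and luteal genes read under 0.25 of the lower of replicates 2 and 3, and it lay at least 4-fold above all WT arrays for 159 probe sets and below them for 90, against 57 and 7 in each of the others. RNA degradation of this array beyond the others is argued against by 3'/5' ratios of 4.38 for Actb and 8.93 for Gapdh, within the ranges of the other 5 arrays (3.93 to 5.45 and 5.24 to 9.62). Its Gapdh ratio was above those of FORKO replicates 2 and 3 (5.24 and 6.69), while WT replicate 1 had higher ratios of both genes. The mean Actb ratio was 4.61 ± 0.774 in WT and 4.59 ± 0.608 in FORKO arrays (SD, n = 3). The mean Gapdh ratio was 7.65 ± 2.16 in WT and 6.95 ± 1.86 in FORKO arrays. These ratios were compared only between arrays and not with an outside bound. Degradation shared by all arrays was therefore not tested and is not excluded. A loss of all granulosa cells as large as the median of 0.056 of the 9 granulosa genes under 0.25 is argued against by Foxl2 and Amhr2. These read 1.04 and 1.33 times the lower of replicates 2 and 3. The argument holds only as far as granulosa cells alone make Foxl2 and Amhr2, which whole-ovary signals do not show. Both were chosen after their values were seen, and Inha read 0.504 and Kitl 1.42 times that lower signal, so a smaller loss is not excluded. A wrong genotype label alone would not account for these low readings. All 11 genes under 0.25 other than Fshr lay below 0.5 of the lowest WT array (median ratio 0.0463), such as Inhba (54.2, WT 2046 to 4332) and Fst (42.0, WT 908 to 1527). These genes were picked for low signals in this array and read low against both groups, so they cannot tell its genotype. Of 850 probe sets called without this array, granulosa and luteal genes left out, it was nearer to the other FORKO arrays for 61.4%. Held out in the same way, WT arrays gave 3.61% to 11.6%, and FORKO replicates 2 and 3 gave 80.5% and 98.6%. The 61.4%, and 56.7% of the 104 with at least 4-fold change, had been set a bound of 75% and missed it. A wild-type ovary in an unusual state is therefore not excluded by them. The test against the lowest WT array was chosen after both. A different state of that ovary, such as one without large follicles, stays open too, since the labels give no measure of it.

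Genes known from male reproductive tract or gland secretions were among the largest rises (Svs5, Klk1b21, Klk1b24, Klk1b27), with Eppin, of the epididymis, rising by 2.28. Male tissue or a mislabelled male is argued against, since 0 of 9 probe sets of the Y-linked Eif2s3y, Kdm5d and Uty lay above the highest WT array in all 3 FORKO arrays (highest signal 16.1) and Xist read 1760 to 2070 on all 6. Probe sets shared between near-identical kallikreins stay open: of 6 other Klk1b probe sets 1 rose by at least 1.45, the bound set, but none passed the dim filter, and their signals of at most 29.7 exclude nothing. Oviduct carried over with the ovaries could account for part in FORKO replicates 2 and 3, where 4 of 5 oviduct genes lay above the highest WT array in both; in replicate 1, which had the highest signal of all 8 genes compared, Ovgp1 read 27.2, within the WT range, while 4 of the other 4 list members lay above it, so it stays open there too. A response of the ovary to the lost receptor was not separated from these.

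Of the genes nearest to Fshr on its chromosome, 3 passed, Adcyap1, Srbd1 and Tmem178, and all 3 fell, with Adcyap1 the largest fall among named genes. DNA of another strain carried along with the deleted gene may account for such a group, but only if the deletion was made in another strain. Both groups came from the same breeding of heterozygotes on the background named above. If the deletion was made in that background, little DNA of another strain would be expected near Fshr. The strain in which it was made was not examined here. The test compared 53 neighbours (50 on one side and 3 on the other, where the chromosome's tested genes ended) with 11145 other genes: 5.66% against 2.12% passed (two-sided Fisher's exact test, p = 0.104; odds ratio 2.77, 95% interval 0.55 to 8.68). The bound written beforehand read a p of 0.05 or more as counting against it; with 53 neighbours in place of 50 on each side and an interval reaching 8.68, that bound was too strict, and the explanation and an effect of the lost receptor cannot be told apart here.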
